A study of Mus musculus with 2 samples.

How the data were processed

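Single-cell RNA sequencing of flow-sorted colonic lamina propria B cells was analysed from 2 libraries, 1 per group, made with the 10x Chromium Single Cell 3′ kit version 2, per the labels' protocols. The groups were day 0 (untreated control) and day 14 (7 days of 2% DSS in drinking water and 7 days of recovery). The treatment tag reads DSS for both samples, and the groups follow the titles, protocols and series design.

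The deposited count matrices hold UMI counts per gene and barcode, made with Cell Ranger 3.0.1 per the file headers, on genome build mm10 per the submitters' processing notes. Annotation, alignment and cell-calling settings are not given in the sources used here. The deposited log-normalized tables hold natural log values, ln(1 + UMIs × 10000 / total UMIs of the cell), as checked from the values. Seurat 3.0 is named in the submitters' processing notes. All 53946130 day 0 values and 76934724 day 14 values compared matched the count matrices within a relative tolerance of 0.001. These tables cover 16416 genes and leave out 86 of 3376 barcodes at day 0 and 88 of 4780 at day 14 by a filter that is not stated. The natural log tables served here to define the cell set, and all levels were computed from the counts.

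The cell set, clustering, class markers, gene lists, the rule for named genes and most alternatives were fixed before the data were examined. Counts of both libraries were scaled to 10000 per cell and log-transformed. The 2000 most variable genes without immunoglobulin, mitochondrial and ribosomal protein genes gave 20 principal components, 20 exact nearest neighbours, a shared-neighbour graph and Leiden clusters at resolution 0.800 (Scanpy 1.11.5, leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0). This gave 11 clusters. A cluster took the name of the class with most markers among its 10 leading genes, where at least 3 of that class were among its 25 leading genes. Cell cycle and mature B cell markers gave no class name of their own. The germinal center B-like cluster had as many cell cycle as germinal center markers among its 10 leading genes. The 9 clusters that stayed unnamed were pooled. Leading genes were ranked against all other cells, so markers shared by most sorted B cells were unlikely to lead a cluster. Scrublet, a doublet caller, marked 0 of 3376 and 0 of 4780 barcodes and so did not work here. No doublets were removed, and cells with more than 2 times the median UMIs of their cluster were left out in an alternative instead.

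Raw counts were summed per library over the pooled cells and divided by all UMIs of genes other than immunoglobulin and mitochondrially encoded genes. Ratios are day 14 over day 0 with exact conditional 95% intervals, sums have exact Poisson intervals and shares exact Clopper-Pearson intervals. These cover counting error only, and with 1 library per group there was no test. A gene with no count in a library was set to a floor of 3 counts per library, which gives a lower bound. Genes with at least 50 UMIs over both libraries were counted, and a ratio of at least 1.50 either way was called higher or lower as a description of size. The named genes are the 12 with the highest lower bound and the 12 with the lowest upper bound of the ratio, leaving out immunoglobulin, mitochondrial, ribosomal protein and predicted (Gm or Rik) genes. The values of 1 gene taken by this rule are not given. Of each list up to 4 measured members with the largest difference and the 1 most abundant member were also taken. Irf1, Nlrc5, Igtp, Irgm1, Gbp2, Ciita and Slfn5 are named besides this rule and were chosen after their values were seen.

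The 20 gene lists were read through members with at least 20 UMIs. The median log2 ratio of a list was placed among 10000 random lists of the same size drawn from 20 expression bins, as a description of these libraries, and the range beside a median is its 95% order-statistic interval over members. Shares of cells above a UMI number were compared after thinning each cell to 1000 UMIs. The heavy chain class of a plasma-like cell is the constant gene with at least 10 UMIs and over 50% of heavy chain constant UMIs. Variable gene use was read from the gene with at least 3 UMIs, and its effective number is Simpson's, with equal cell numbers drawn 1000 times. Of 31053 gene IDs, 31011 (99.9%) were found in GENCODE M21, which gave the mm10 positions.

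Gene ratios and list medians were tested on simulated counts. Over 8782 genes, 50 of 50 genes made 2-fold higher and 45 of 46 made 0.500-fold were called, as were 50 of 50 made 4-fold higher and 46 of 46 made 0.250-fold. Of 8590 unchanged genes, 98 (1.14%) passed 1.5-fold higher and 61 (0.710%) lower. Over 9912 genes, 8 of 200 unchanged lists fell outside the central 95% of random lists, and 50 of 50 lists raised 1.5-fold lay above it. The simulated genes varied independently and by counting error only. Members of real lists can vary together between 2 single libraries, so this does not check the percentiles of real lists. Several real lists lay outside the central 95%, among them glycolysis (percentile 98.1) and mitochondrially encoded genes (98.9). A percentile alone is thus no evidence of regulation.

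Alternatives covered the cell set, cluster resolution (0.400 and 1.50), genes used to cluster, denominator, TMM (edgeR 4.0.16) and median-of-ratios scaling, equal weight per cell, thinning, UMI minimums, the cells of high UMI number, and cells weighted so that clusters built without genes 1.5-fold apart had equal shares on both days. Computation used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. The left-out barcodes entered only an alternative and the closing observations.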

Results

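B cells were sorted by flow cytometry from the colonic lamina propria, the connective tissue layer beneath the gut epithelium, of female C57BL/6J mice, and their transcripts were counted cell by cell on the 10x Chromium 3′ platform. The control library came from untreated mice at day 0. The recovery library came from mice at day 14, after 7 days of 2% dextran sulfate sodium (DSS) in the drinking water and 7 days of recovery. DSS is a polysaccharide that damages the colonic epithelium and induces colitis. Both samples carry the same DSS treatment tag, and the untreated state of day 0 is taken from the sample protocols and the series design. Each group holds 1 library, and the number of mice behind a library is not given in the sources used here. The day 0 library held 3290 cells with 8690102 unique molecular identifiers (UMIs, each standing for 1 captured transcript), a median of 2278 UMIs and 895 genes per cell. The day 14 library held 4692 cells with 12317052 UMIs, a median of 2242 UMIs and 859 genes per cell. With 1 library per group no difference below has a replicate check, and the 95% intervals given in parentheses cover counting error only.

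The first comparison asks which kinds of B lineage cells were present at day 0 and after recovery. A small cluster led by germinal center and cell cycle genes was less frequent at day 14, and plasma-like cells, named by Edem1, Txndc5 and Fkbp11, took similar shares on both days. Plasma-like cells were 25 of 3290 (0.760%, 0.492 to 1.12) at day 0 and 31 of 4692 (0.661%, 0.449 to 0.937) at day 14, so no difference was detectable at this depth. Germinal center B-like cells, named by Rgs13, Mef2b and Basp1 and led equally by cell cycle genes, were 35 of 3290 (1.06%, 0.742 to 1.48) at day 0 and 18 of 4692 (0.384%, 0.228 to 0.606) at day 14. Some genes that lead both clusters differed in level between the days, so the cells were also grouped without the 907 genes that were at least 1.5-fold apart. The plasma-like numbers were then identical. The cluster led by Rgs13, Mef2b, Pclaf and Top2a in that grouping held 30 of 3290 cells (0.912%, 0.616 to 1.30) at day 0 and 16 of 4692 (0.341%, 0.195 to 0.553) at day 14. The naming rule calls it germinal center B-like. Since 4 cell cycle against 3 germinal center markers were among its 10 leading genes, its share was not counted among the alternatives. The shares are those of sorted B cells, and the gate sets which plasma cells enter them.

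The remaining 9 clusters had too few leading marker genes for a name and were pooled for the comparison of expression. The pool held 3230 cells at day 0 and 4643 cells at day 14. At least 5 UMIs of mature B cell markers were found in 3230 and 4640 of them. Cd79a, a component of the B cell receptor, was detected in 97.8% of cells on both days, and Ms4a1, which encodes CD20, in 74.1% at day 0 and 76.5% at day 14. Of these clusters, 3 were led by genes whose levels were within 1.5-fold on both days, and their sizes are set side by side here. Another cluster, led by Serpina3g, Tgtp2 and Serpina3f, held 0.517% of cells at day 0 and 9.21% at day 14. The cells it took can lower the day 14 shares of the other clusters. The cluster led by Gpr183, Tnfaip3 and Icosl held 649 cells (19.7%, 18.4 to 21.1) at day 0 and 653 (13.9%, 12.9 to 14.9) at day 14. The cluster led by the activation genes Egr1, Myc and Nfkbid held 188 cells (5.71%, 4.95 to 6.56) and 260 (5.54%, 4.90 to 6.23). The cluster led by Srm, Pa2g4 and Mif held 120 cells (3.65%, 3.03 to 4.35) and 189 (4.03%, 3.48 to 4.63). The pool was made up differently on the days: in the grouping without genes 1.5-fold apart, a cluster led by Slfn2, Tmem108 and Ube2d1 held 435 cells (13.2%, 12.1 to 14.4) at day 0 and 1293 (27.6%, 26.3 to 28.9) at day 14. With the shares of that grouping's clusters made equal, the median log2 ratios of the interferon-gamma and type I interferon lists described below were 0.9747 and 0.345, and 129 genes were higher and 350 lower.

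The second comparison asks how gene expression of the pooled B cells at recovery differed from that of untreated mice. Genes tied to interferon-gamma dominated the higher side: of the 12 genes highest by the lower bound of their ratio, 6 were in the interferon-gamma list (Serpina3f, Serpina3g, Tgtp1, Tgtp2, Ifi47 and Gbp7) and Zbp1 was in the type I interferon list. On the lower side stood the G protein signalling regulators Rgs1 and Rgs13, the chemokine gene Ccl4, the linker histone gene Hist1h1c and Ltc4s, which encodes leukotriene C4 synthase. The pool gave 7671748 UMIs at day 0 and 11165017 at day 14 after immunoglobulin and mitochondrial genes were set aside, and levels are given as CPM over these UMIs. Of 8784 genes with at least 50 UMIs, 124 (1.41%) were at least 1.5-fold higher and 387 (4.41%) at least 1.5-fold lower at day 14. The median gene had a log2 ratio of -0.08. Of unchanged genes in the simulated counts, 1.14% passed 1.5-fold higher and 0.710% lower. The simulated genes were centred at a log2 ratio of -0.002, unlike the real ones. The shares are therefore not directly comparable and do not tell how many higher genes reflect counting error. Among genes with at least 200 UMIs, 41 were higher and 103 lower. The split into higher and lower genes depended on the scaling. With TMM factors 207 genes were higher and 234 lower. With median-of-ratios factors, which moved the median of all genes by 0.10 on the log2 scale, 213 were higher and 223 lower.

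Among the higher genes, the serpin gene Serpina3g (ENSMUSG00000041481) went from 16.4 CPM (13.7 to 19.5) to 85.2 CPM (79.9 to 90.8), a ratio of 5.19 (4.30 to 6.30). The nucleic acid sensor gene Zbp1 had a ratio of 4.15 (3.28 to 5.31), the immunity-related GTPase gene Ifi47 of 3.33 (2.61 to 4.28) and the guanylate-binding protein gene Gbp7 of 3.28 (2.36 to 4.65). Serpina3f (mm10 chromosome 12, 104214544 to 104221129) had 4 UMIs at day 0 and 203 at day 14, a ratio of 34.9 (13.4 to 129.2). The GTPase gene Tgtp2 (mm10 chromosome 11, 49057194 to 49064206) had 12 and 254 UMIs, a ratio of 14.5 (8.18 to 28.5), and Tgtp1 had 1 and 59. Tgtp1 and Tgtp2, and likewise Serpina3f and Serpina3g, are related genes whose reads may be hard to tell apart. How the counts divide within each pair was not checked. Outside the interferon lists, Ffar2, a receptor for short-chain fatty acids, had a ratio of 8.44 (3.93 to 21.6), and Cfp, which encodes the complement regulator properdin, a ratio of 2.71 (2.17 to 3.42). S100a8 and S100a9, the calprotectin genes abundant in neutrophils, had no UMI at day 0 and 263 and 125 UMIs at day 14, at least 60.2-fold and 28.6-fold higher against a floor of 3 counts. Of these, 256 S100a8 UMIs and 119 S100a9 UMIs lay in 2 barcodes, and without these 2 barcodes the bounds were at least 1.60-fold and 1.37-fold.

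Among the lower genes, Rgs1 (ENSMUSG00000026358, mm10 chromosome 1, 144242296 to 144249242) went from 107.9 CPM (100.7 to 115.5) to 42.9 CPM (39.1 to 46.9), 2.52-fold lower (2.24 to 2.82). Hist1h1c was 2.46-fold lower (2.24 to 2.70), Crisp3 3.20-fold lower (2.70 to 3.82) and Ltc4s 5.28-fold lower (2.99 to 9.83). Ccl4 had 125 UMIs in 23 cells at day 0 and 57 UMIs in 28 cells at day 14, 3.19-fold lower (2.32 to 4.45), with up to 27 UMIs in a single cell. Rgs13, typical of germinal center B cells, had 46 and 21 UMIs, 3.19-fold lower (1.86 to 5.62). The other 6 genes named by the rule were Myadm (4.06-fold lower), Ly6c2 (3.82-fold), Rpap2 (2.97-fold), Zrsr1 (2.95-fold), AY036118 (2.44-fold) and Rgcc (2.32-fold). Ly6c2 had 42 and 16 UMIs, with 13 in a single cell. It also led the plasma-like cluster, and free RNA of plasma cells was not taken off its values. Rgs1 leads a small cluster, together with Basp1, Nt5e and Cd80, that was less frequent at day 14 (3.65% and 1.85% in the grouping without genes 1.5-fold apart). With cluster shares made equal, Rgs1 was 2.003-fold lower, and Basp1 (1.49-fold lower), Nt5e (1.43-fold) and Cd80 (1.15-fold), given as lower below, lay within 1.5-fold.

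**Figure D1:**
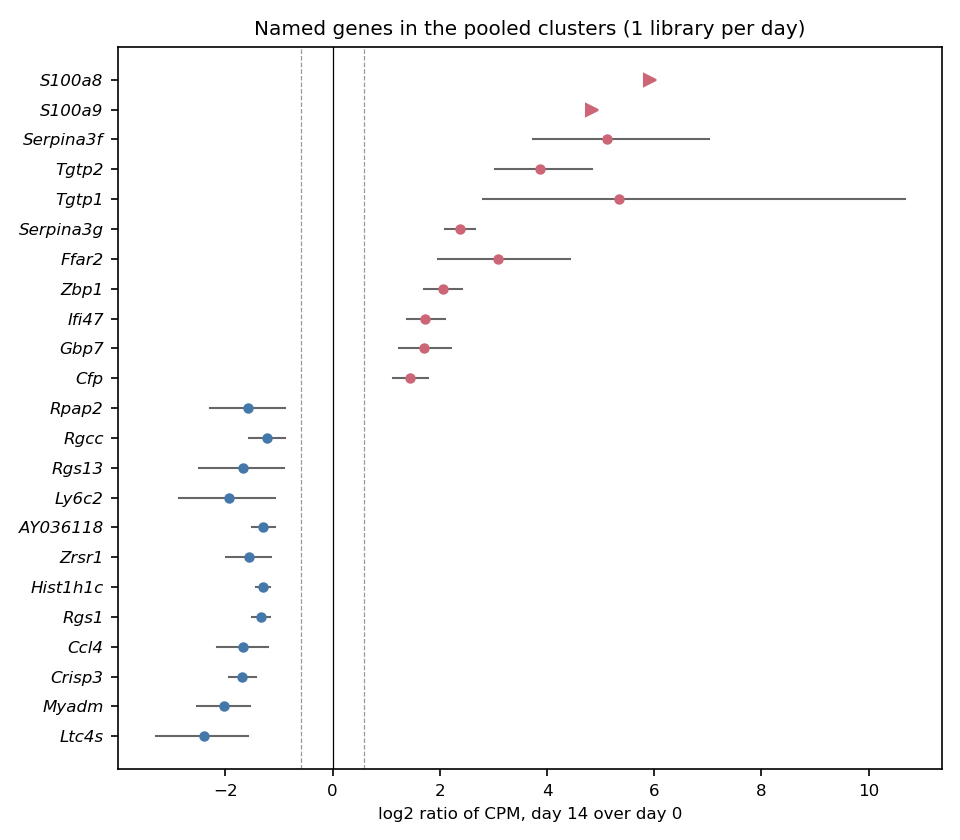
Log2 ratio of CPM, day 14 over day 0, in the pooled clusters for the named higher and lower genes; points are ratios, bars 95% counting intervals, dashed lines 1.5-fold, and triangles lower bounds for genes with no UMI at day 0. Serpina3g sits at 2.38 and Rgs1 at -1.33.

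Interferon-gamma-associated genes were higher at day 14 as a group. Of 26 measured members, 17 were at least 1.5-fold higher, 1 was lower and 8 lay within 1.5-fold. The median log2 ratio was 0.94 (0.46 to 1.73, the range of the median over members), above all of 10000 random lists of the same size and expression, whose central 95% ran from -0.19 to 0.02. Besides the genes above, the higher members included Irf1 (2.06, 1.82 to 2.35), a transcription factor induced by interferon, and Nlrc5 (3.44, 1.92 to 6.60), the transactivator of MHC class I genes. The GTPase genes Igtp and Irgm1 had ratios of 2.93 and 2.23, Gbp2 had 2.68, and Iigp1 went from 0 to 23 UMIs, at least 5.27-fold. The most abundant member, the proteasome activator gene Psme1, had a ratio of 1.47 (1.38 to 1.56). The lower member was Ciita, the transactivator of MHC class II genes, at 0.622 (0.557 to 0.694), which lay within 1.5-fold with median-of-ratios factors. Summed over the list, the level went from 1016 to 1417 CPM, a ratio of 1.40 (1.36 to 1.43). Of the pooled cells, 17 at day 0 and 432 at day 14 formed a cluster led by genes of this list, mostly from the day 14 library, and without it the summed ratio was 1.178 (1.145 to 1.212).

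Type I interferon-stimulated genes, a list with 0 genes in common with the former, were higher to a smaller extent. Of 47 measured members, 12 were at least 1.5-fold higher, 1 was lower and 34 lay within 1.5-fold. The number of higher members depended on the scaling, with 18 higher and 1 lower under TMM or median-of-ratios factors. The median log2 ratio was 0.35 (0.21 to 0.51 over members), also above all of its random lists. Besides Zbp1, at 4.15, large ratios were seen for members with few UMIs: Lgals3bp (2.62, 1.33 to 5.65) and Ifit3 (2.52, 0.991 to 7.59) rested on 42 and 22 UMIs at day 14. The most abundant member, Ifi27l2a, had a ratio of 1.31 (1.24 to 1.38). Slfn5 was lower, at 0.578 (0.363 to 0.916). The summed ratio of the list was 1.23 (1.21 to 1.26).

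**Figure D2:**
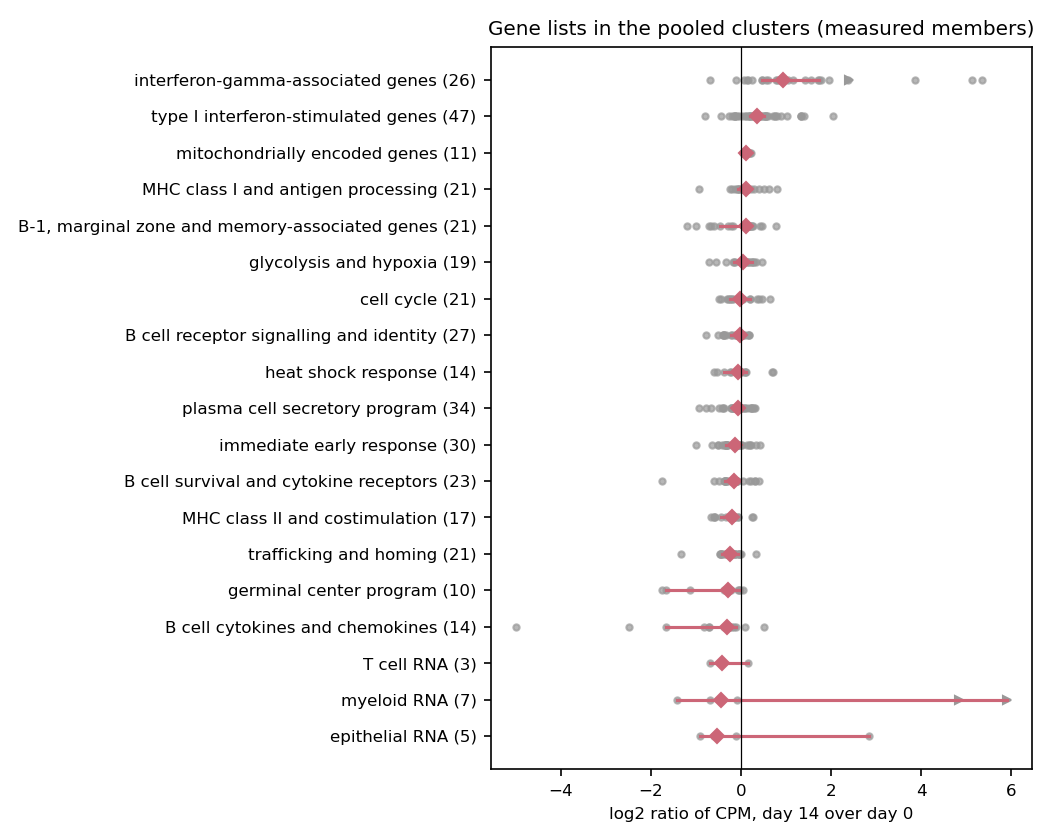
Median log2 ratio of day 14 over day 0 for each gene list with measured members in the pooled clusters; diamonds are medians, bars their 95% ranges over members, grey points single members and triangles lower bounds, with the number of measured members in parentheses. The interferon-gamma list at 0.94 and the type I interferon list at 0.35 lie highest.

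The interferon-gamma list was higher in every pooled cluster and unevenly spread over single cells. With clusters built without the genes of both interferon lists, the summed list was higher at day 14 in 9 of 9 pooled clusters, with ratios from 1.15 to 1.64 and every interval above 1. In germinal center B-like cells of that grouping (33 and 18 cells) the ratio was 1.11 (0.907 to 1.37), not a detectable difference. The type I list had a ratio of 1.78 (1.47 to 2.17) in these cells. That list was higher in 9 of 9 pooled clusters of the same grouping, 8 with the interval above 1. In the original grouping it was higher in 7 of 9, 6 with the interval above 1. The lowest ratio there, 0.720 (0.636 to 0.819), was in the cluster led by genes of the interferon-gamma list. Each cell was then thinned to 1000 UMIs, which left out 34 and 63 shallower cells. Cells with at least 5 UMIs of the interferon-gamma list were 19 of 3196 (0.595%, 0.358 to 0.927) at day 0 and 151 of 4580 (3.30%, 2.80 to 3.86) at day 14. Next to that limit, 66 and 233 cells had 4 or 5 UMIs. Cells with at least 8 UMIs were 0 of 3196 and 29 of 4580 (0.633%, 0.425 to 0.908). The mean was 0.940 UMIs at day 0 and 1.33 at day 14, with a variance over mean of 1.13 and 1.61. Serpina3g was detected in 1.19% of thinned cells at day 0 and 6.73% at day 14 (3.44% and 13.9% unthinned). No class in these libraries is known to lack this transcript, so no background share can be set beside it.

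**Figure D3:**
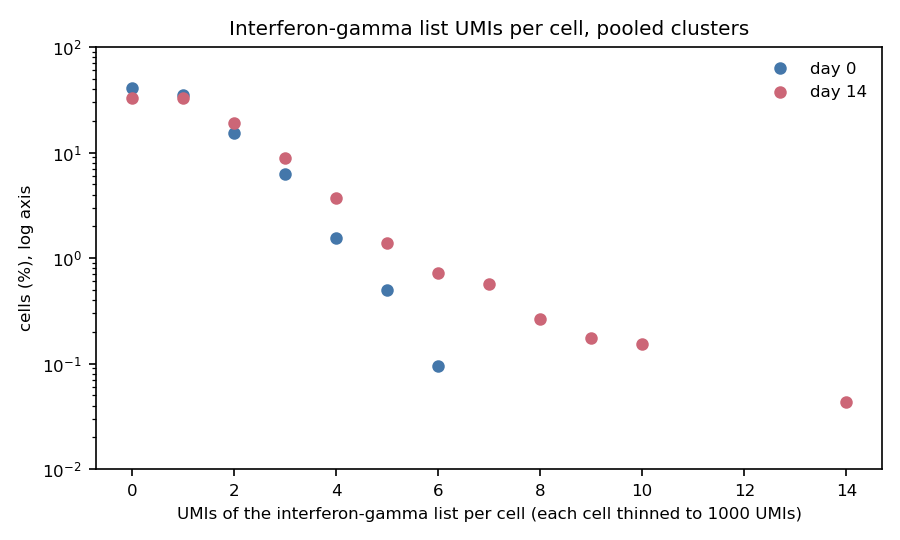
Share of pooled cells (percent, log axis) by the number of interferon-gamma list UMIs per cell, each cell thinned to 1000 UMIs; points are the day 0 and day 14 libraries. At 5 or more UMIs lie 0.595% of day 0 cells and 3.30% of day 14 cells.

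**Figure D4:**
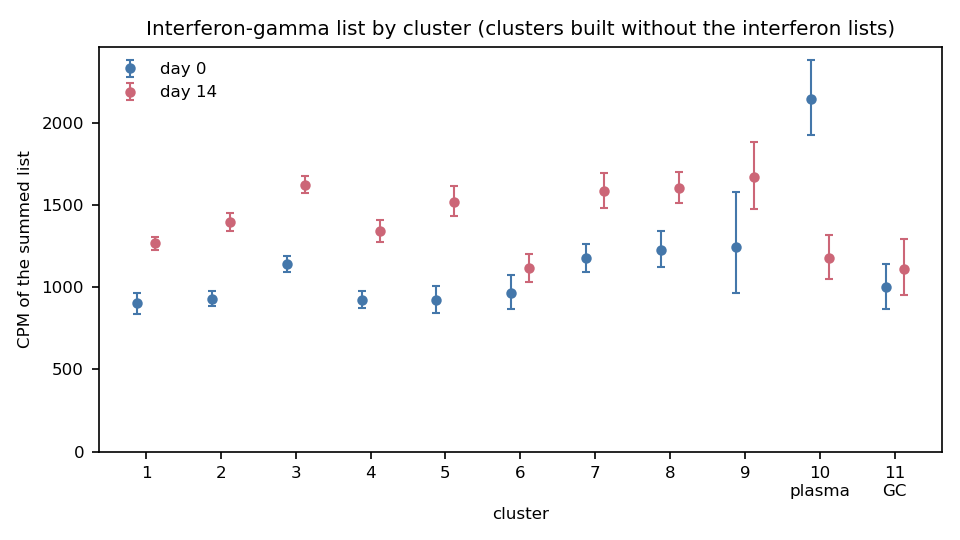
Summed CPM of the interferon-gamma list per cluster and day, with clusters built without the interferon lists; points are libraries and bars 95% counting intervals. Day 14 lies above day 0 in clusters 1 to 9, and below it in the plasma-like cluster 10.

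MHC class I genes had a slightly higher and MHC class II and costimulation genes a slightly lower median. Of 21 class I and antigen processing genes, 2 were at least 1.5-fold higher, namely the peptide transporter gene Tap1 (1.73, 1.54 to 1.95) and the immunoproteasome gene Psmb9 (1.54, 1.40 to 1.70). H2-T24 was lower (0.524, 0.255 to 1.05), and 18 lay within 1.5-fold, among them B2m (1.10, 1.08 to 1.11). The class I median log2 ratio was 0.10 (percentile 99.97). Of 17 class II and costimulation genes, 3 were at least 1.5-fold lower and 14 lay within, with a median of -0.20 (percentile 0.170). The lower members were Cd80 (0.626, 0.435 to 0.898), Cd40 (0.656, 0.571 to 0.754) and Pdcd1lg2 (0.663, 0.563 to 0.780), and the peptide-loading gene H2-DMb1 followed at 0.668. With TMM or median-of-ratios factors 0 of the 17 passed 1.5-fold, and the most abundant member, Cd74, lower at 27322 CPM against 28756, turned to a ratio of 1.02. Also, with cells thinned to 1000 UMIs, Cd80 turned to 1.75, from 10 and 25 UMIs.

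Trafficking and homing genes were lower as a group, with a median log2 ratio of -0.25 at percentile 0, below all random lists. Of 21 measured, 1 was at least 1.5-fold lower (Rgs1) and 20 lay within, among them Ccr7 (0.749, 0.726 to 0.773), the receptor that guides cells into lymphoid tissue, Klf2 (0.730, 0.707 to 0.754) and the gut-homing integrin gene Itgb7 (0.727, 0.641 to 0.826). Cytokine and chemokine genes had a median of -0.32 (percentile 0.540), with 0 higher, 6 lower and 8 within. Ccl22 had 22 UMIs at day 0 and 1 at day 14, with 15 in a single cell. Spp1 had 23 and 6, with 11 in a single cell, and Il4i1 had a ratio of 0.563 (0.453 to 0.698). Germinal center program genes had a median of -0.29 (percentile 2.58), with 3 of 10 lower and 7 within: Myb (14 and 6 UMIs), Rgs13 and Basp1 (0.457, 0.353 to 0.588). Survival and cytokine receptor genes had a median of -0.17 (percentile 1.38), with 2 of 23 lower, Bcl2l1 (21 and 9 UMIs) and Cd40, and 21 within. Immediate early genes had a median of -0.13 (percentile 1.58), with Atf3 (27.2 to 13.6 CPM) and Dusp1 (0.644, 0.572 to 0.726) lower, 28 of 30 within and 0 higher. With TMM or median-of-ratios factors Cd40 and Dusp1 lay within 1.5-fold.

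Genes of B cell receptor signalling and identity did not stand apart from random lists. Of 27, 26 lay within 1.5-fold, and 1, Fcer2a, which encodes the low-affinity IgE receptor CD23, was lower, from 319.7 to 186.0 CPM, a ratio of 0.582 (0.549 to 0.617). The median was -0.03 (percentile 49.1). In the list of B-1, marginal zone and memory-associated genes, 5 of 21 were at least 1.5-fold lower, among them Bhlhe41 (0.436, 0.321 to 0.590), a transcription factor of B-1 cells, and Nt5e (0.502, 0.359 to 0.699), which encodes the ectoenzyme CD73. Ptpn22 was higher (1.70, 1.45 to 2.00) and 15 lay within, with Plac8 at 1.13. The median of that list was 0.10 (percentile 99.9), against its lower members, and turned to -0.08 without cells of high UMI number and to -0.15 with members of at least 1 UMI. With TMM or median-of-ratios factors 3 of its members were lower. Heat shock genes had a median of -0.06 (percentile 38.0), with Hspa1a (1.63) and Hspa1b (1.61) higher, Hsph1 (0.664) lower and 11 of 14 within. With those factors Hsph1 lay within 1.5-fold. The heat shock and B cell receptor medians turned positive (0.04 and 0.07) with median-of-ratios factors.

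Cell cycle genes had 1 of 21 members higher (Pclaf, 7 and 16 UMIs) and 20 within, with a median of -0.03 (percentile 80.6). With cluster shares made equal Pclaf lay within 1.5-fold, at 1.35. Plasma cell secretory genes had 3 of 34 lower and 31 within, with a median of -0.07 (percentile 38.7), and both medians turned positive (0.07 and 0.03) with median-of-ratios factors. The secretory members lower were Sdc1 (0.523, 0.407 to 0.671), Fkbp11 (0.580, 0.334 to 0.999) and Trib3 (12 and 11 UMIs). Trib3 lay within 1.5-fold with TMM or median-of-ratios factors and turned to 1.63 in thinned cells. Sdc1 and Fkbp11 were also leading genes of the plasma-like cluster. Free RNA of plasma cells, raised below for Igha, was not taken off their values. Glycolysis and hypoxia genes had a median of 0.05 (percentile 98.1), with 18 of 19 within and Vegfa lower (17 and 15 UMIs), which turned to 1.16 in thinned cells. The 11 mitochondrially encoded genes all lay within 1.5-fold, with a median of 0.12 (percentile 98.9).

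T cell, epithelial and stromal transcripts were scarce in the pool. The T cell list had 83 UMIs at day 0 and 67 at day 14, with 3 members measured, of which Trac was lower (0.622, 0.316 to 1.21). The epithelial list had 135 and 171 UMIs and 5 measured members, with Muc2 higher (2 and 21 UMIs, ratio 7.22, 1.76 to 63.5), Phgr1 (0.534) and Lgals4 (0.656) lower and 2 within. The stromal list had 5 and 27 UMIs and no member with enough UMIs to be measured. In the myeloid list S100a8 and S100a9 were higher, Apoe (1005 to 621.0 CPM, 0.618, 0.598 to 0.638) and Fcer1g (24 and 13 UMIs) were lower, and 3 of 7 lay within. A single day 0 cell held 15 of the Fcer1g UMIs. The myeloid list summed to 9578 and 9729 UMIs, mostly Apoe, with Cst3 at 1332 and 1834 UMIs and Tyrobp, named outside the rule like Cst3, at 482 and 518. Fcer1g turned to 1.14 with every cell weighted equally, Lgals4 lay within 1.5-fold with TMM or median-of-ratios factors, and Trac did so with the latter. The medians were -0.42 for T cell, -0.54 for epithelial and -0.44 for myeloid genes, at percentiles 28.3, 10.1 and 0.465.

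The third comparison asks which antibody classes the plasma-like cells expressed. IgA predominated on both days, and cells dominated by an IgG gene were found at day 14 alone. Igha was the dominant heavy chain gene in 24 of 25 cells (96.0%, 79.7 to 99.9) at day 0 and in 22 of 31 (71.0%, 52.0 to 85.8) at day 14. IgG genes dominated in 0 of 25 cells (exact upper bound 13.7%, or 12% by a floor of 3 counts) and in 5 of 31 (16.1%, 5.45 to 33.7): Ighg1 in 2, Ighg2b in 2 and Ighg3 in 1. Ighm dominated in 1 and 2 cells, and 2 day 14 cells were unassigned. The kappa light chain gene Igkc dominated in 24 of 25 and 27 of 31 cells and lambda genes in 1 and 3. The intervals of the Igha shares and of the IgG shares overlap between the days. With fewer than 50 plasma-like and germinal center B-like cells per library, genes were not ranked within these classes.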

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

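The comparison of plasma-like with pooled cells, the genes named in the former and the 3 tests in this part were chosen after the results were seen. The summed interferon lists differed in opposite directions in the pool and in the plasma-like cells. The summed interferon-gamma list had a day 14 over day 0 ratio of 1.40 in the pooled clusters and of 0.548 (0.468 to 0.641) in the plasma-like cluster, where it went from 2145 to 1176 CPM. The type I interferon list had ratios of 1.23 and 0.573 (0.520 to 0.631). The difference between the cell groups was not tested, and the plasma-like values come from 25 and 31 cells. In these cells the chemokine gene Cxcl10 had 121 UMIs at day 0 and 18 at day 14, with up to 43 in a single cell, and Bst2 had 376 and 160 UMIs. Ifitm3 went the other way, with 11 and 57 UMIs. Without Cxcl10 the interferon-gamma ratio of the plasma-like cluster was 0.788 (0.659 to 0.942). That value still holds Serpina3g, higher in the pool but lower here, with 31 and 14 UMIs (ratio 0.289, 0.142 to 0.559). The intervals of all other members of that list with at least 20 UMIs in these cells included 1. The lower type I sum rests on Bst2 and Ly6a (277 and 258 UMIs): without Bst2 the ratio was 0.797 (0.707 to 0.897), and without both genes it was 1.04 (0.880 to 1.23), not a detectable difference.

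The higher interferon-gamma list in the pooled B cells was weighed against 3 technical explanations. RNA of epithelial or stromal cells was not among them and was not tested. Free RNA added alike to every cell would give 1.60% of day 14 cells with at least 5 list UMIs, and 3.30% (2.80 to 3.86) were observed. This covers the rise of the whole pool, including the cluster led by genes of the list. It cannot tell whether the smaller rise in the other pooled cells, a ratio of 1.178 (1.145 to 1.212), came from free RNA. Transcripts of T cells or myeloid cells in the pool, summed over 24 genes without Apoe, S100a8 and S100a9, had a ratio of 0.872 (0.821 to 0.926). This lay below the 1.40 of the list. Also without Cst3 and Tyrobp, which hold most of these UMIs, the ratio was 0.616 (0.479 to 0.793). Reads shared between gene copies are argued against as the source of the whole rise. The 17 members without the Serpina3, Tgtp and Gbp genes still had a median log2 ratio of 0.55. The central 95% of random lists ended at 0.04. A response of B cells to interferon-gamma during recovery from colitis may account for the pattern, as a hypothesis found in these same data that no test here decides: B cells without the interferon-gamma receptor, in replicate libraries per day, would be needed. The difference in handling between the libraries stays open, since each day is a single library.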

How the results depend on the processing

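Among the alternatives, the cells of high UMI number left out, the 2 S100a8-rich barcodes left out, the cluster led by Rgs1 left out, the cluster shares made equal, and the clusterings without the interferon lists or without genes 1.5-fold apart were chosen after seeing the data. All 24 alternative values of the plasma-like and germinal center B-like shares and all 6 of the Igha share of plasma-like cells lay within the intervals of the reported values. The interferon-gamma median stayed between 0.79 and 1.05 and the type I median between 0.31 and 0.45. Of 264 list medians 13 moved outside their interval, mostly with TMM or median-of-ratios factors. Of 144 values for the 12 lower named genes all passed 1.5-fold, as did 138 of 140 for the higher ones, the exceptions being S100a9 without the 2 barcodes and with all deposited barcodes (at least 1.37-fold in both). The numbers of higher and lower genes were 236 and 671 at a minimum of 20 UMIs and 41 and 103 at 200, because other numbers of genes were counted, and 207 and 234 with TMM and 213 and 223 with median-of-ratios factors, which shift all ratios. Of 1240 gene ratios 1136 stayed within their interval, 100 moved and 4 reversed. The 4 were Cd80 (1.75), Trib3 (1.63) and Vegfa (1.16) in cells thinned to 1000 UMIs, and Fcer1g (1.14) with cells weighted equally. For Fcer1g, 15 of its 24 day 0 UMIs lay in a single cell. The cause of the reversals was not tested. With cluster shares made equal 11 of 104 gene ratios and 0 of 19 list medians moved, and of the genes named in the text Cd80, Cd40, Pdcd1lg2, Dusp1, Hsph1, Basp1, Pclaf, Trib3, Nt5e and Vegfa came within 1.5-fold. Without the cluster led by Rgs1 4 ratios moved and Rgs1 was 1.93-fold lower. Thinning left 10 and 25 Cd80 UMIs, 3 and 7 of Trib3 and 3 and 5 of Vegfa. Of 6 values of the effective number of variable genes 3 moved, since other numbers of cells were assigned and drawn. The share of cells with a Serpina3g UMI moved in 3 of 4 values, since it rises with depth, and stayed higher at day 14 (0.8669% and 3.597% at 500 UMIs). All 4 values of the share of pooled cells with an Igha UMI moved for the same reason and stayed lower at day 14 (9.57% and 3.40% at 500 UMIs). Removal of called doublets gave no value, since none were called. With all deposited barcodes the plasma cluster mixed with stromal genes and gave no share or isotype. The germinal center B-like share of the clustering without genes 1.5-fold apart, given above, was left out of the 24 values. Cell cycle markers outnumbered germinal center markers among the leading genes of that cluster. The Ighv minimum of 10 UMIs left too few cells. No paired analysis was possible because the result comes from no test, with 1 library per group.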

Other observations

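The tests on S100a8 and Igha transcripts in this part, and the choice of the class-switched and left-out cells, were made after the data were seen. A small cluster of the pool, led by Rgs1, Rrad, Basp1, Nt5e, Cd80 and Cd44, was rich in class-switched B cells and less frequent at day 14. Grouped without the genes that were 1.5-fold apart, it held 120 of 3290 cells (3.65%, 3.03 to 4.35) at day 0 and 87 of 4692 (1.85%, 1.49 to 2.28) at day 14. In the original grouping 69 of its 145 day 0 cells (47.6%, 39.2 to 56.0) and 44 of its 91 day 14 cells (48.4%, 37.7 to 59.1) had at least 3 Igha or Ighg UMIs and more of these than of Ighm and Ighd. Over the whole pool such cells were 92 of 3230 (2.85%, 2.30 to 3.48) and 65 of 4643 (1.40%, 1.08 to 1.78), a count that includes any free Igha RNA, since no background was taken off. By Ighg alone they were 0.774% (0.501 to 1.14) and 0.495% (0.314 to 0.742), which overlap, and outside that cluster 0.227% and 0.242%. Ighg3 had 5 UMIs at day 0 and 73 at day 14 in the pool without that cluster, and 0 and 3280 UMIs in plasma-like cells, where 2 cells held them.

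Kappa variable genes of plasma-like cells were less even at day 14, by an amount that depended on the minimum of UMIs. Igkv1-110 was the dominant gene in 8 of 20 assigned day 14 cells, and the effective number of Igkv genes at 16 cells was 9.85 at day 0 and 4.91 at day 14. With a minimum of 1 UMI it was 10.3 and 7.44 at 21 cells, and with 10 UMIs 6.00 and 4.92 at 6 cells. For Ighv genes, assigned in 18 and 11 cells, it was 8.44 and 5.26 at 11 cells, and with a minimum of 1 UMI 11.8 and 9.52 at 20 cells. The barcodes absent from the submitters' log-normalized tables were largely T cells: 59 of 86 (68.6%) at day 0 and 48 of 88 (54.5%) at day 14 had at least 5 UMIs of T cell markers, against 1 of 3230 and 0 of 4643 pooled cells. Grouped with all barcodes, 60 and 50 of them fell in T cell-like and 10 and 12 in epithelial-like clusters.

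S100a8 and S100a9 were present in the pool at day 14 alone. If they came from free RNA, their UMIs would be spread over many cells, but 97.3% of S100a8 UMIs lay in 2 barcodes, which argues against that source. The same 2 barcodes held 13 UMIs (6.92 to 22.2) of the 6 other neutrophil markers, where the rate of the other pooled cells gives 0.0267. They held 786 and 550 UMIs in all and 0 of Cd79a and Ms4a1; other B cell genes were not examined in them. A few neutrophils may have passed the sort for B cells, and no biological explanation within B cells was tested.

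Igha UMIs in the pool without the class-switched cluster were lower at day 14, at 0.443 UMIs per cell at day 0 and 0.153 at day 14. Depth is argued against, since at 1000 UMIs per cell 16.9% (15.6 to 18.3) of day 0 cells and 5.46% of day 14 cells had an Igha UMI, and IgA-switched B cells are argued against, since 4.94% (3.72 to 6.41) of the day 0 cells with an Igha UMI had no Ighm or Ighd UMI. Free RNA of plasma cells may account for it: at day 0 Igha was found alike in cells with at least 3 Ighm or Ighd UMIs (35.8%, 33.8 to 37.8) and in cells with none (35.3%, 27.7 to 43.6). Jchain in the same pooled cells went from 135.8 to 48.1 UMIs per 1000 cells. Igha UMIs of plasma-like cells per cell of the library were 2.52 times higher at day 0, near the 2.89 times of the pooled cells. Plasma cells lost before capture, which could also release this RNA, cannot be counted in these data.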
